A study of Mus musculus with 6 samples.

How the data were processed

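Small RNA libraries of mouse embryonic stem cells were sequenced, 1 library for each of 6 groups. Per the labels' protocols, adapters were ligated to the small RNA and the bands of miRNA inserts and of somewhat longer small RNAs were both taken from a gel. The deposited tables give counts per mature miRNA, and per the file headers each count is the number of reads that matched 1 entry (unique matches) or several entries (multi-matches). The aligner, the mismatches allowed, the miRBase version, the genome build and any filter on reads are not given in the sources used here. Without a genome build no coordinates are given, and miRNAs are named as in the files. The values used are the unique-match counts as deposited, which are whole numbers with a different total in each library. Multi-match counts were used only in an added alternative, since a read that fits several entries is entered at each of them. Near-identical miRNAs can still share reads or lose them to the multi-matches.

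Each file lists 1899 entries, of which 12 stand for several miRNAs with identical mature sequences and are named with a slash. No read was counted in any library for 701 entries. The 351 entries with a mean count of at least 50 over the 6 libraries were analysed. This mean is of unscaled counts, so WT with RA, the deepest library, weighs most in it. A miRNA can pass the minimum through its reads in that library alone. They held between 99.6% and 99.8% of the reads of each library. Total counts ran from 83626 to 6106104, and 3 counts, the limit that a count of 0 allows, equalled 2.75, 2.13, 2.65, 0.882, 0.448 and 27.8 normalised CPM (counts scaled to a common library size) in untreated WT, untreated Wt1 KO, dox 12 h, dox 24 h, WT with RA and Wt1 KO with RA.

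Counts were scaled by the trimmed mean of M values (TMM) over the 6 libraries, in edgeR 4.0.16 under R 4.3.3, with factors of 1.02, 0.798, 0.922, 0.937, 1.10 and 1.29 in the same order. Log2 ratios were taken with a prior count of 0.5 per library. With 1 library per group edgeR's test has no estimate of the spread, so no test of a difference between groups, standard error or p-value is given. The 1 exact binomial test used, on reads carried over between libraries, covers counting error only. Each ratio has a 95% interval from the exact conditional binomial (Clopper-Pearson), which covers counting error only. Shares of reads have Wilson intervals in the tables. The median width of the ratios' intervals to either side was 0.32 for untreated Wt1 KO against WT, 0.27 for RA in WT, 0.80 for RA in Wt1 KO, 0.76 for Wt1 KO against WT with RA, 0.34 and 0.25 for dox at 12 h and 24 h, and 0.29 for 24 h against 12 h. Where a library had no read, the fold is given as a bound from 3 counts in that library. The difference between the RA responses of the genotypes has an interval by the delta method on its 4 counts.

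The 7 comparisons, the size rule (log2 ratio of at least 1 or at most -1 with an interval that excludes 0), the lists and the alternatives were fixed before the data were examined. Named miRNAs are the 10 higher and the 10 lower per comparison whose interval bound lies farthest from 0, up to 4 members of each list with the highest mean count, and the 10 most abundant over the 6 libraries. Other miRNAs named in the text were chosen after their values were seen. The 23 lists were the miR-290 cluster, the miR-302 cluster, the miR-17 clusters and paralogs, the let-7 family, miR-99/100 and miR-125, neural miRNAs, HOX clusters, miRNAs reported to target pluripotency factors, the Dlk1-Dio3 locus, the Sfmbt2 intron cluster, the miR-200 family, the miR-183 cluster, the miR-15/16 family, the miR-130 and miR-301 family, kidney-enriched miRNAs, miR-34 and miR-449, the X-linked testis cluster and miRNAs of non-canonical biogenesis. They also included markers of muscle and mesoderm, fibroblast and mesenchyme, blood and endothelium, and endoderm, and entries reported to overlap rRNA or tRNA. A list's median is given with its percentile among 10000 random lists of the same size, for the 20 lists with 3 or more measured members. The random lists were matched in 10 bins on the mean unscaled count over the 6 libraries. Since WT with RA weighs most in this mean, the match is not independent of the RA comparisons. The percentile describes these libraries and is no test. Members of a cluster, and the arms of a hairpin, can come from a shared transcript and move together, while random lists draw miRNAs singly. The number of members that are higher or lower is thus not repeated evidence.

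For comparisons that share the untreated Wt1 KO library, 100 sets of libraries without any effect were simulated from counting error, and the shared library's reads were also split in 2 at random. Alternatives to these choices were scaling as CPM of the total, by the median of ratios (DESeq2 1.42.0), or as CPM without the miR-290 and miR-302 clusters. Others were a minimum mean count of 10 or 200 or none, a prior count of 5, a size rule of 1.5, and thinning of all libraries to 83626 reads. Chosen after seeing the data were unique plus multi-matches, a correction for GC content and length, and TMM without the Wt1 KO library with RA.

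The calculations were tested on simulated counts for the 351 miRNAs with 200 of them altered. Of those altered by a log2 of 1.5, 86.4% were called for untreated Wt1 KO against WT, 98.5% for RA in WT, 60.9% for RA in Wt1 KO, 55.4% for Wt1 KO against WT with RA, 95.8% and 94.0% for dox at 12 h and 24 h, and 98.5% for 24 h against 12 h. None was called the wrong way. Of 151 unaltered miRNAs 6 were called for RA in Wt1 KO, 4 for Wt1 KO against WT with RA, 2 for untreated Wt1 KO against WT and 0 in the other comparisons. The intervals covered the true ratio, shifted by the error of the scaling, for 95.4% to 97.4% of miRNAs. This coverage therefore leaves the scaling error out. In the simulation the scaling was off by -0.25 for RA in Wt1 KO and by -0.11 for Wt1 KO against WT with RA. Further work used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9. All 6 libraries were used and none was left out.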

Results

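Mature microRNAs (miRNAs) were counted by small RNA sequencing in 6 libraries of mouse embryonic stem cells. The cells were wild-type (WT) 129/Ola cells, or cells in which Wt1 was knocked out (KO). Wt1 encodes a zinc finger transcription factor needed for kidney and gonad development. The 6 groups, with 1 library each, were untreated WT, untreated Wt1 KO, WT with retinoic acid, Wt1 KO with retinoic acid, and Wt1 KO cells with an inducible Wt1 after 12 h or 24 h of doxycycline. Retinoic acid (RA), a derivative of vitamin A that drives stem cells to differentiate, was given at 1 µM (the labels write 1 µm, read here as micromolar), and doxycycline (dox), which switches on the inducible gene, at 1 µg/ml. How long RA was given is not stated in the sources used here. The cells grew on gelatin with serum and leukemia inhibitory factor, so no feeder cell layer is named. Small RNA libraries do not measure the Wt1 mRNA, so neither the knockout nor the induction of Wt1 was checked here. No dox-treated library of cells without the transgene is used here. The labels do not say which clone carries the inducible gene, so the untreated Wt1 KO library, the reference for dox, may come from another line than the dox libraries, and the dox ratios and the count of miRNAs that return toward WT may include a difference between lines.

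Depth differed 73.0-fold between the deepest and the shallowest library. The total number of uniquely matched reads was 1063945 in untreated WT, 1768862 in untreated Wt1 KO, 1227428 after 12 h of dox, 3629658 after 24 h of dox, 6106104 in WT with RA and 83626 in Wt1 KO with RA. Of 1899 mature miRNA entries, 351 had a mean count of at least 50 over the 6 libraries and were analysed. The median count of these 351 miRNAs ran from 132 to 876 in the other 5 libraries and was 16 in Wt1 KO with RA. The Wt1 KO library with RA is therefore the least precise, and a count of 3 there equals 27.8 normalised CPM, against 0.448 in WT with RA. With 1 library per group no difference has a replicate check. A miRNA is called higher or lower by size, when its log2 ratio is at least 1 or at most -1 and its 95% counting interval excludes 0. Intervals are given in brackets and cover counting error only, since reads amplified by PCR without molecular identifiers are not independent molecules. Every comparison below is between libraries, not between conditions.

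miR-92a-3p and miR-127-3p were the most abundant miRNAs over the 6 libraries. miR-92a-3p took 20.1% of the reads in untreated WT, 35.1% in untreated Wt1 KO, 24.6% and 22.6% after 12 h and 24 h of dox, 6.71% in WT with RA and 12.7% in Wt1 KO with RA. The miR-290 cluster, the main miRNA cluster of mouse embryonic stem cells, held 16.8% of the reads in untreated Wt1 KO, at most 23.4% in the 4 libraries without RA, 0.751% in WT with RA and 9.40% in Wt1 KO with RA. The miRNAs of the HOX clusters held at most 0.0461% without RA, 10.9% in WT with RA and 2.41% in Wt1 KO with RA. The imprinted Dlk1-Dio3 locus, which includes miR-127-3p, held 24.1% to 26.6% without RA, 34.6% in WT with RA and 44.6% in Wt1 KO with RA.

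The comparison of untreated Wt1 KO with untreated WT cells asks which miRNAs differ where Wt1 is missing. miR-181a-5p and miR-21a-5p were among the abundant miRNAs that were much lower in Wt1 KO, with log2 ratios of -3.93 [-4.06 to -3.80] and -2.98 [-3.13 to -2.83]. The miR-99/100 and miR-125 families, the miR-200 family and the miR-302 cluster were lower as groups. Members of the miR-17 clusters and their paralogs, which promote proliferation, were higher, and so were members of an X-linked cluster known from testis. In all, 43 of the 351 miRNAs were higher and 54 lower.

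Of the 9 measured members of the miR-99/100 and miR-125 families, 7 were lower in untreated Wt1 KO and none was higher. miR-99b-5p had a log2 ratio of -1.51 [-1.54 to -1.49], miR-125a-5p of -1.68 [-1.71 to -1.64] and miR-125b-5p of -2.31 [-2.59 to -2.04]. The list median was -2.31, below all 10000 random lists of the same size and mean count, or -1.70 with members without a read set at their bound. All 3 measured members of the miR-302 cluster, a cluster of primed pluripotent cells, were lower, with a median of -2.27 at percentile 0.66 of the random lists. Of the miR-200 family, which keeps the epithelial state, 5 of 7 members were lower (median -1.73, percentile 0.185), among them miR-200b-3p at -1.73 [-1.80 to -1.65] and miR-429-3p at -2.42 [-2.71 to -2.15]. The fibroblast and mesenchyme list had 5 of 7 members lower (median -1.92, percentile 0.045), namely miR-21a-5p, miR-21a-3p, miR-22-3p, miR-31-5p and miR-222-3p, while miR-199a/b-3p was at 0.68 [0.16 to 1.24]. Of the 2 measured members of the muscle and mesoderm list, miR-143-3p was at 1.08, or 0.72 as CPM of the total, and miR-133a-3p at -3.61 [-4.66 to -2.81]. miR-335-3p had the lowest ratio with reads in both libraries, -5.38 [-6.82 to -4.43], from 243 reads in WT and 7 in Wt1 KO. miR-181a-1-3p had 18 reads in WT and 0 in Wt1 KO, at least 7.77-fold lower. miR-92a-1-5p, the minor arm of a miR-92a hairpin, was at -3.71 [-3.97 to -3.48].

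Of 21 measured members of the miR-17 clusters and paralogs, 9 were higher in untreated Wt1 KO and 1 lower (median 0.69, percentile 99.9). miR-92a-3p was at 1.17 [1.16 to 1.17], miR-20b-5p at 1.84 [1.63 to 2.07] and miR-106a-5p at 1.79 [1.58 to 2.01], and the lower member was miR-92a-1-5p. The shares of reads of miR-92a-3p, 20.1% in untreated WT and 35.1% in untreated Wt1 KO, lie less than 2-fold apart, so its call is lost as CPM of the total. The X-linked testis cluster had 3 of 4 members higher (median 1.37, percentile 99.6), with miR-470-5p at 1.93 [1.58 to 2.29]. Of 66 members of the Dlk1-Dio3 locus 9 were higher and none lower (median 0.41, percentile 99.9). The miR-290 cluster had no member past the size rule, while 12 of its 13 members had positive ratios and its median of 0.62 lay at percentile 99.4. The blood and endothelium list had 2 of 4 members higher (median 1.16, percentile 99.0), among them miR-150-5p at 1.83 [1.73 to 1.94]. Scaling moved this comparison: as CPM of the total, the median of all miRNAs shifted by -0.35 and the split became 25 higher and 76 lower, and without the miR-290 and miR-302 clusters in the total it shifted by -0.34 and the split became 26 and 76.

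**Figure D1:**
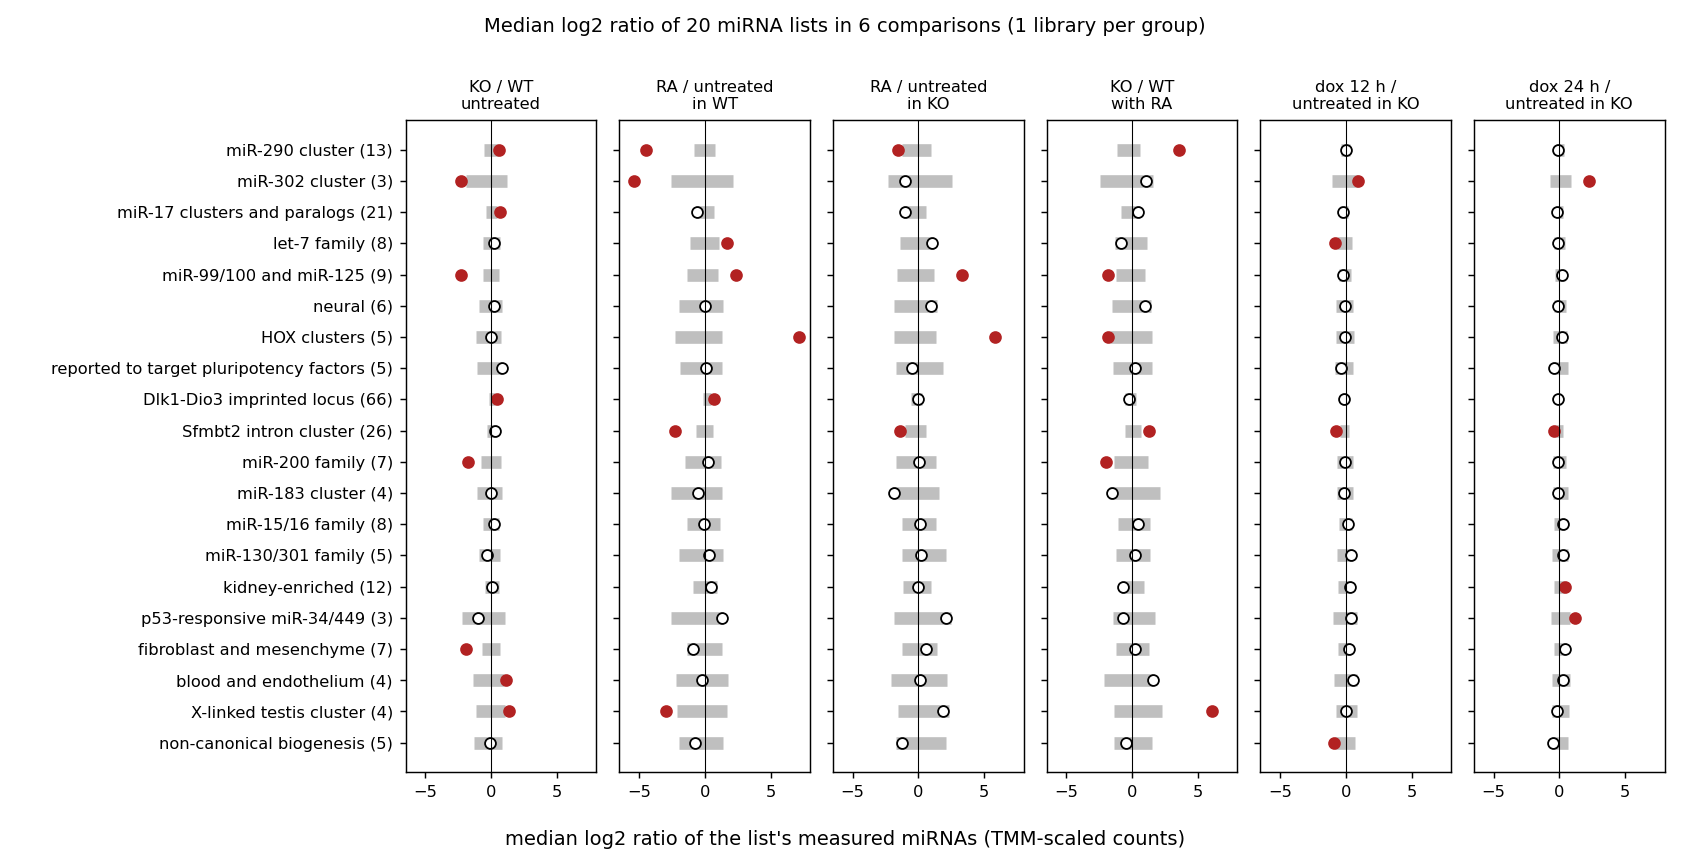
Median log2 ratio of the measured members of 20 miRNA lists (member numbers in brackets) in 6 comparisons of 2 libraries each, from TMM-scaled counts. Grey bars span the middle 95% of 10000 random lists matched on size and mean unscaled count, filled points lie outside them and open points inside. With RA the miR-290 cluster lies at -4.46 in WT and -1.52 in Wt1 KO and the HOX clusters at 7.17 and 5.86, and several open points near 0 change sign with the scaling.

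RA was compared with no treatment in WT cells to describe the miRNA response of differentiating cells. The stem cell clusters were far lower and the miRNAs of the HOX clusters far higher with RA. miR-10a-5p, encoded in a HOX cluster, stood out with 66 reads in untreated WT and 491094 with RA, a log2 ratio of 10.24 [9.89 to 10.61]. All 13 measured members of the miR-290 cluster and all 3 of the miR-302 cluster were lower. By the size rule 79 miRNAs were higher and 85 lower. The minimum mean count favours miRNAs with many reads in WT with RA, the deepest library.

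The median of the miR-290 cluster was -4.46, below all random lists, and that of the miR-302 cluster -5.39, at percentile 0.255. The most abundant member, miR-295-3p, was at -4.30 [-4.32 to -4.27], miR-291a-5p at -5.62 [-5.68 to -5.56] and miR-302d-3p at -5.39 [-5.78 to -5.04]. All 26 measured miRNAs of the cluster in an intron of Sfmbt2, a large rodent miRNA cluster, were lower with RA (median -2.24), among them miR-466g at -2.44 [-2.68 to -2.21] and miR-467a-5p at -1.69 [-1.87 to -1.51]. All 4 members of the X-linked testis cluster were also lower (median -2.94, percentile 0.365). Of the miR-17 clusters and paralogs, 8 of 21 members were lower and none higher (median -0.61, percentile 2.91), with miR-92a-3p at -1.68 [-1.69 to -1.67] and miR-106a-5p at -3.90 [-4.29 to -3.55].

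Of the 5 measured miRNAs of the HOX clusters, 4 were higher with RA (median 7.17 at percentile 99.995, or 7.04 with miR-10a-3p at its bound). miR-10b-5p was at 7.04 [6.83 to 7.26], miR-615-3p at 7.17 [6.65 to 7.75] and miR-10a-3p at least 44.1-fold higher, while miR-196a-5p was at 0.90. The let-7 family, which accompanies differentiation, had 6 of 8 members higher and none lower (median 1.67, percentile 99.9), with let-7c-5p at 2.69 [2.58 to 2.80]. The miR-99/100 and miR-125 families had 5 of 9 members higher (median 2.38, percentile 99.995), among them miR-99a-5p at 7.03 [5.72 to 8.95] and miR-125b-5p at 3.29 [3.16 to 3.41]. miR-181a-5p was at 2.92 [2.89 to 2.96]. Of the Dlk1-Dio3 locus 25 of 66 members were higher and 1 lower (median 0.68, percentile 99.9). Of the markers of other cell types, both measured members of the muscle and mesoderm list were higher, miR-133a-3p and, at 1.14, miR-143-3p, as was the endoderm marker miR-375-3p at 1.82 [1.49 to 2.17]. The fibroblast and mesenchyme list had 3 of 7 members lower and 1 higher (median -0.91, percentile 4.62), and the blood and endothelium list 1 of 4 lower and none higher (median -0.18). Without the miR-290 and miR-302 clusters in the total, the median of all miRNAs shifted by -0.14.

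In Wt1 KO cells with RA most HOX cluster miRNAs were again higher and most of the miR-290 cluster lower, with list medians smaller in size than in WT. Of the 5 measured HOX members, 3 had a weaker response in Wt1 KO by the size rule. miR-10a-5p had 102 reads untreated and 1443 with RA in a far shallower library, a log2 ratio of 7.52 [7.24 to 7.83]. miR-181a-5p and miR-181b-5p, lower in untreated Wt1 KO, were higher with RA, at 5.70 [5.56 to 5.84] and 5.76. In this comparison 82 miRNAs were higher and 81 lower.

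Of the 5 miRNAs of the HOX clusters 4 were higher (median 5.86, percentile 99.995), with miR-10b-5p at 5.39 [5.11 to 5.70] and miR-615-3p at 5.86 [5.28 to 6.59]. By the upper bound of miR-335-3p, 12.3% of this library's reads could be reads of the WT library with RA. That would equal 57.6% of this library's miR-10a-5p reads. The bound was the lowest of 165 abundant miRNAs and was not adjusted for that choice, so both shares may be larger. Of the miR-99/100 and miR-125 families 6 of 9 members were higher (median 3.32, percentile 99.995), with miR-125b-5p at 3.32 [2.95 to 3.70] and miR-99a-5p at least 170-fold higher. Of the let-7 family 4 of 8 were higher (median 1.05, percentile 96.6). The fibroblast and mesenchyme list had 3 of 7 members higher, miR-199a/b-3p at 3.84 [3.44 to 4.27] among them, and both muscle list members were higher, miR-143-3p at 2.97 and miR-133a-3p at 4.60. The endoderm marker miR-375-3p was higher, at 1.38, and the blood and endothelium list had 1 member higher and 1 lower. miR-6240, an entry reported to overlap ribosomal RNA and listed here as a sign of RNA quality, was also higher, at 2.74.

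Of the 13 miR-290 cluster miRNAs 10 were lower with RA in Wt1 KO (median -1.52, percentile 0.72), with miR-295-3p at -1.14 [-1.19 to -1.09] and miR-292a-3p at -2.31 [-2.43 to -2.20]. None of the 3 miR-302 members passed the size rule (median -1.05, or -0.65 with the member without a read at its bound). Of the Sfmbt2 intron cluster 16 of 26 members were lower and 1, miR-467a-5p, higher (median -1.41, percentile 0.275). All 4 measured miRNAs of the miR-183 cluster, known from sensory cells, were lower (median -1.82, percentile 4.42), among them miR-182-5p at -1.61 [-1.68 to -1.54]. The miR-17 clusters and paralogs had 9 of 21 members lower and 2 higher (median -1.05, percentile 5.52), and miR-150-5p was at -3.85 [-4.53 to -3.25]. Of the Dlk1-Dio3 locus 12 members were higher and 12 lower, and its median of -0.06 flips sign with the scaling. The balance of calls in this comparison depended on the scaling: the split was 124 higher and 34 lower as CPM of the total (shift of the median 0.69), 91 and 62 by the median of ratios (shift 0.17), and 113 and 42 without the miR-290 and miR-302 clusters (shift 0.56).

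**Figure D2:**
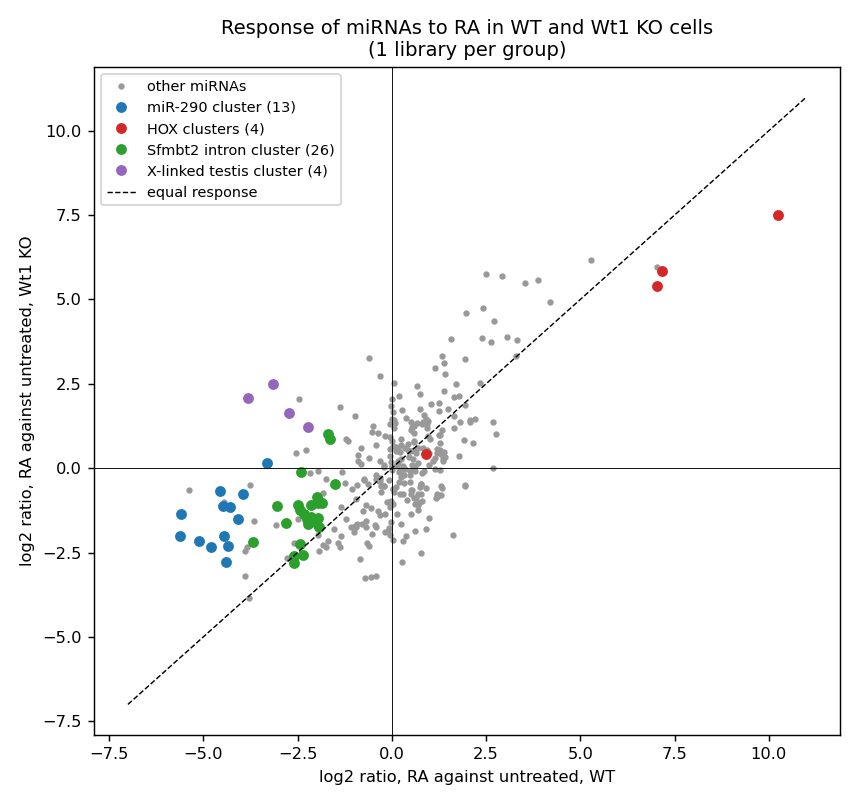
Log2 ratio of RA against untreated in WT (x axis) and in Wt1 KO (y axis) for 338 miRNAs, 1 point each, without the 13 that had no read in 1 of the 4 libraries; the dashed line marks equal responses. The 13 miR-290 cluster miRNAs lie above the line, near -4.46 in WT and -1.52 in Wt1 KO, and the 4 X-linked testis cluster miRNAs are negative in WT and positive in Wt1 KO.

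With RA in both, Wt1 KO was compared with WT to find where the treated cells differ. The miR-290 cluster was much higher in Wt1 KO, and most measured members of the miR-99/100 and miR-125 families, the miR-200 family and the HOX clusters were lower. The X-linked testis cluster had the highest median ratio of the 20 lists with 3 or more measured members. By the size rule 63 miRNAs were higher and 68 lower.

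All 13 miR-290 cluster miRNAs were higher in Wt1 KO than in WT with RA (median 3.53, above all random lists), with miR-295-3p at 3.26 [3.21 to 3.31] and miR-291a-3p at 4.32 [4.08 to 4.56]. All 4 X-linked testis cluster miRNAs were higher (median 6.10, above all random lists), with miR-470-5p at 6.29 [5.86 to 6.76] and miR-465c-5p at 7.31 [6.27 to 8.85], the latter from 8 reads in WT and 23 in Wt1 KO. The Sfmbt2 intron cluster had 11 of 26 members higher (median 1.32, above all random lists). Of the HOX clusters 3 of 5 members were lower (median -1.85, percentile 1.23), miR-10a-5p at -2.46 [-2.53 to -2.38], miR-10b-5p at -2.51 [-2.65 to -2.37] and miR-615-3p at -1.85. The other 2 had positive ratios, miR-10a-3p, the other arm of the miR-10a hairpin, at 0.29 [-0.53 to 0.99] and miR-196a-5p at 0.99 [0.20 to 1.68]. Of the miR-99/100 and miR-125 families 6 of 9 were lower (median -1.82, percentile 0.155), of the miR-200 family 5 of 7 (median -1.98, percentile 0.175) and of the miR-183 cluster 4 of 4 (median -1.53, percentile 4.49). miR-200b-3p was at -3.24 [-3.62 to -2.88] and miR-335-3p at -4.23 [-5.45 to -3.25]. miR-199a/b-3p and miR-143-3p were higher, at 2.98 and 2.92 [2.76 to 3.07], while the fibroblast and mesenchyme list had 1 of 7 members higher and 1 lower (median 0.21). The blood and endothelium list had 2 of 4 higher (median 1.57, percentile 97.15). The miR-6240 entry was higher as well. Alternative scalings gave 81 higher and 42 lower as CPM of the total (shift 0.24), 78 and 51 by the median of ratios (shift 0.20), and 92 and 38 without the stem cell clusters (shift 0.37).

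Between untreated and RA-treated libraries, 23 miRNAs were lower in Wt1 KO in both states, against 10.5 for independent lists, and 18 were higher in both, against 7.72. These 2 contrasts share no library. Across the 351 miRNAs, which are not independent replicates, the contrasts had a Pearson r of 0.36 and a Spearman rho of 0.43.

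The response to RA itself was set against that of the other genotype for each miRNA. The log2 response was higher by at least 1 in Wt1 KO for 76 miRNAs and lower for 65, with intervals that exclude 0. This split depended on the scaling, with 125 and 28 as CPM of the total, 88 and 50 by the median of ratios, and 131 and 23 without the stem cell clusters. All 13 miR-290 cluster miRNAs were among the 76 (median difference 3.16), with miR-295-3p at 3.16 [3.11 to 3.21], as were 6 of 7 fibroblast list members (median 2.03, percentile 99.5), both muscle list members, miR-143-3p at 1.83 and miR-133a-3p at 2.64, and miR-6240, the entry listed as a sign of RNA quality, at 3.06 [2.78 to 3.33]. Of the HOX clusters 3 members had a weaker response in Wt1 KO (median -1.65), with miR-10a-5p at -2.72 [-3.17 to -2.27], and 2 did as CPM of the total and 1 without the stem cell clusters. Of the Dlk1-Dio3 locus 21 members had a lower and 4 a higher response (median -0.71, percentile 0.01), among them miR-541-5p at -1.88 [-1.96 to -1.80]. As CPM of the total these were 11 and 9 (median -0.11), and without the stem cell clusters 8 and 10, with a median of 0.0091 that flips sign, while the locus's share of reads was 26.6% untreated and 44.6% with RA in Wt1 KO, and 24.1% and 34.6% in WT. The 2 responses had a Pearson r of 0.64 and a Spearman rho of 0.58 across miRNAs, and 44 miRNAs were higher and 46 lower in both genotypes, against 18.5 and 19.6 for independent lists. No miRNA was higher in WT and lower in Wt1 KO, while 7 were lower in WT and higher in Wt1 KO.

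Dox-treated Wt1 KO cells were compared with untreated Wt1 KO cells to see which miRNAs follow the induced Wt1. After 12 h, miR-92a-1-5p was far higher, with a log2 ratio of 5.51 [5.28 to 5.76], and miR-409-5p and miR-501-3p were far lower, at -4.12 [-4.80 to -3.55] and -3.51 [-3.96 to -3.12]. After 24 h all 3 measured miR-302 cluster miRNAs were higher. The counts were 15 higher and 31 lower at 12 h, and 20 higher and 13 lower at 24 h. Most miRNAs, 305 and 318 of the 351, were neither. These calls allow for counting error only, and the arms of a hairpin differed by more than that under dox, as given below.

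Untreated Wt1 KO held 107 normalised CPM of miR-92a-1-5p, and the other 5 libraries between 787 and 4884. Of the markers of other cell types, 1 fibroblast list member was higher and 1 blood list member lower at 12 h, and none passed the size rule at 24 h. At 12 h miR-290a-3p was at 2.00 [1.76 to 2.27] and miR-302b-3p at 1.49 [0.85 to 2.21], while the miR-290 cluster as a whole had a median of 0.04. Of the Sfmbt2 intron cluster 8 of 26 members were lower (median -0.74, percentile 0.01), with miR-466d-3p at -1.10 [-1.52 to -0.71]. Of the let-7 family 2 of 8 were lower (median -0.83, percentile 0.49), let-7c-5p at -1.70 [-1.88 to -1.52] and let-7a-5p at -1.20 [-1.71 to -0.72]. miR-99b-5p was at -1.46 and miR-224-5p at -2.56 [-3.73 to -1.65]. The miR-6240 entry was higher at 12 h, at 1.33, and at 0.21 at 24 h. The balance at 12 h turned with the scaling, to 35 higher and 13 lower as CPM of the total (shift 0.20), 21 and 23 by the median of ratios (shift 0.07), and 44 and 9 without the stem cell clusters (shift 0.32).

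At 24 h the miR-302 cluster had a median of 2.24 (percentile 99.9), with miR-302b-3p at 2.45 [1.91 to 3.07] and miR-302a-3p at 2.24 [1.82 to 2.70]. Of the p53-responsive list of miR-34 and miR-449 2 of 3 members were higher (median 1.15, percentile 99.8), miR-34b-3p at 2.38 [1.33 to 3.79] and miR-34c-5p at 1.15 [0.98 to 1.32], while miR-34a-5p was at 0.10 [-0.02 to 0.23]. miR-181a-5p was at 1.18 [1.05 to 1.32] and miR-92a-1-5p at 2.88 [2.64 to 3.13]. Lower miRNAs included miR-409-5p at -3.84 [-4.20 to -3.53], miR-501-3p at -2.62 [-2.83 to -2.43] and miR-96-5p at -1.56 [-1.83 to -1.29]. The Sfmbt2 intron cluster had 2 of 26 members lower, and its median of -0.40 (percentile 0.19) turned to 0.085 with a mean count of at least 200. As CPM of the total the split was 31 higher and 10 lower (shift 0.23), and 37 and 6 without the stem cell clusters (shift 0.30).

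The 24 h library, set against the 12 h library, had 15 miRNAs higher and 3 lower. Of the miR-302 cluster 2 of 3 members were higher (median 1.32), with miR-302d-3p at 1.53 [1.29 to 1.78], and of the let-7 family 3 of 8 (median 1.01, above all random lists), with let-7c-5p at 1.06 [0.89 to 1.23]. The 3 lower entries were miR-92a-1-5p at -2.63 [-2.70 to -2.57], miR-5126 at -2.49 [-2.75 to -2.25] and miR-6240 at -1.12 [-1.25 to -0.99]. At both times 6 miRNAs were higher, miR-92a-1-5p, miR-26b-3p, miR-211-5p, miR-290a-3p, miR-27b-5p and miR-302b-3p. Independent lists would share 0.855, and libraries simulated without any effect shared at most 1. Another 10 were lower at both times, against 1.15 for independent lists and at most 1 in the simulations, and none went opposite ways. Both contrasts use the same untreated Wt1 KO library, which cannot be split into separate cultures, so part of the excess over these values may come from it. With its reads split at random, 4 were higher and 9 lower at both times, and the covariance of the log2 ratios was 0.41, against 0.43 unsplit and 0.05 from counting error alone.

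**Figure D3:**
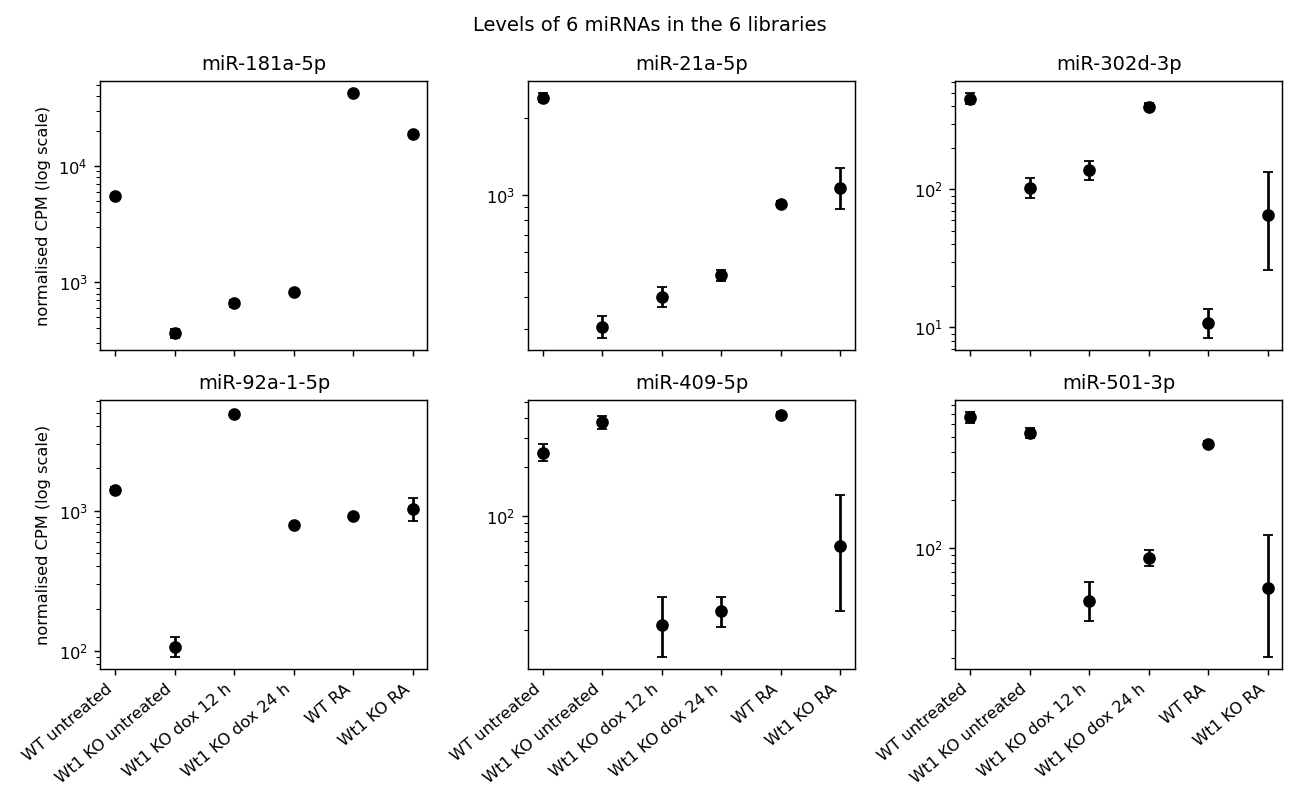
Normalised CPM (log axis) of 6 miRNAs in the 6 libraries, 1 point per library, with exact Poisson 95% intervals for counting error only. miR-92a-1-5p is lowest in untreated Wt1 KO, at 107, and miR-409-5p and miR-501-3p are low in both dox libraries and in Wt1 KO with RA.

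Return toward the WT level under dox was counted among the 97 miRNAs called in untreated Wt1 KO, as a call under dox in the opposite direction. This does not measure the distance from WT, and a miRNA can pass the WT level. miR-92a-1-5p did so at 12 h, with 1408 normalised CPM in untreated WT and 4884 under dox. At 12 h 10 of the 97 returned by this rule, among them miR-92a-1-5p, miR-21a-3p, miR-335-3p and miR-18b-5p, and at 24 h 14 did, among them miR-181a-5p, miR-181b-5p, miR-429-3p and the 3 miR-302 miRNAs. As CPM of the total 20 of 101 called miRNAs returned at each time, by the median of ratios 13 and 14 of 94, and without the stem cell clusters 22 and 20 of 102. Independent lists would give 6.11 and 4.67, or 8.50 and 7.42 as CPM of the total, 5.85 and 4.52 by the median of ratios, and 10.2 and 8.46 without the stem cell clusters, and simulated libraries without an effect at most 2 at each time. Moving further from WT were 5 miRNAs at 12 h and 3 at 24 h, with miR-99b-5p, miR-211-5p and miR-224-5p at both times. Both contrasts again use the untreated Wt1 KO library. With its reads split, 13 miRNAs returned at each time and the covariances were -0.26 and -0.36, against -0.35 and -0.38 unsplit and -0.04 and -0.06 from counting error alone. Splitting reads does not remove the error of the culture.

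Both arms of a hairpin come from 1 precursor, so the difference of their log2 ratios gives a yardstick within the libraries. The standard deviation of this difference was 0.64 over 75 hairpins for untreated Wt1 KO against WT, and 0.81 over 75 for RA in WT. It was 1.06 over 70 hairpins for RA in Wt1 KO and 1.04 over 71 for Wt1 KO against WT with RA, where counting error alone amounts to 0.72 and 0.68. For dox it was 0.90 over 74 hairpins at 12 h and 0.74 over 75 at 24 h, against a counting error of 0.30 at each time. The 2 arms had a Pearson r across hairpins of 0.75 to 0.90 in the comparisons without dox, and of 0.20 and 0.16 for dox at 12 h and 24 h. The median absolute difference for dox was 0.60 at 12 h and 0.38 at 24 h. This difference carries the scatter of both arms, and its cause was not tested. Scatter beyond counting error can thus take a dox ratio past the size rule of 1. The counting intervals and the simulations without an effect leave it out, so dox calls near the size rule are uncertain.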

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

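All of the tests that weigh explanations in this part were chosen after the results were seen. The differences between genotypes given here were not tested, since each group has 1 library.

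Several miRNAs went opposite ways with RA in the 2 genotypes, lower in WT and higher in Wt1 KO. Of these, 4 belong to the X-linked testis cluster. The log2 response in Wt1 KO minus that in WT was 5.89 for miR-465c-5p, 5.67 for the shared 3p entry of miR-465a, miR-465b and miR-465c, 4.36 for miR-470-5p and 3.43 for miR-871-3p. The list's medians were -2.94 in WT and 1.87 in Wt1 KO, which differ by 4.81. For miR-21a-3p the difference was 4.52, for miR-21a-5p 3.19 and for miR-467a-5p, of the Sfmbt2 intron cluster, 2.70. Multi-matched reads, which the comparisons do not use, made up 0.404% of the reads in Wt1 KO with RA (Wilson interval 0.363% to 0.449%), above the 0.341% in untreated WT (0.330% to 0.352%).

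For the weaker response of the miR-290 cluster miRNAs to RA in Wt1 KO, low depth alone is argued against, because with all libraries thinned to the smallest total the miR-290 median was still -4.39 in WT and -1.28 in Wt1 KO. For the weaker response of HOX cluster miRNAs depth was not weighed in this way. Untreated Wt1 KO cells or reads in the RA library, as the whole cause for the median miR-290 member, are argued against by 7 of 69 other abundant miRNAs. These fell below the 30.8% that this member needs, with miR-92a-3p at 22.4% and miR-150-5p at 6.95% of its untreated level. The cluster's members kept 14.6% to 110% of their untreated levels. Members that need less were not weighed, and a smaller share stays open. Reads carried over from the WT library with RA would make the response in Wt1 KO look stronger, not weaker, and as the source of the whole HOX cluster rise they are argued against by 2 of 165 abundant miRNAs, miR-200b-3p and miR-335-3p, which had fewer reads than the smallest share a HOX member needs (20.5%) would bring. This rests on a one-sided exact binomial test adjusted for 165 miRNAs, which covers counting error only. The test replaced, once its result was known, a first rule that asked for more than 5 miRNAs, found 3 and left this undecided. A share of 12.3% stays open, and a larger one may, since this bound was the lowest of 165 and was not adjusted. Lower RNA quality of the Wt1 KO library with RA cannot be told apart. miR-6240, the only measured entry reported to overlap rRNA or tRNA, also differed by 3.06 [2.78 to 3.33]. A weaker response of cells without Wt1 stays open as a hypothesis, beside other cell types. Both muscle list members (1.83 and 2.64) and 6 of 7 fibroblast list members had a higher response too. These differences include the untreated level, since most fibroblast list members and miR-133a-3p were already lower in untreated Wt1 KO. With RA, miR-199a/b-3p and miR-143-3p were higher in Wt1 KO than in WT, but the fibroblast list as a whole was not.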

How the results depend on the processing

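No paired analysis was possible because each group has 1 library, and for the same reason no library could be left out of a group. The planned sum over several entries of 1 miRNA was not run, since no miRNA stands at more than 1 entry. Of 220 counts recomputed under the alternatives, 151 stayed within 1.5 times the first count and 69 did not. Of 1472 list medians in the 7 comparisons, 1303 stayed within the median counting error of their members, 168 moved and 1 reversed. Reversed means a change of sign of a median that first lay outside the middle 95% of random lists, or of a called miRNA. Other medians that changed sign are not counted as reversed, and those of the difference between RA responses are not among the 1472. The reversed median is that of the Sfmbt2 intron cluster at dox 24 h, 0.085 with a mean count of at least 200, and among named miRNAs miR-34b-3p with RA in WT reversed to -1.03 with all libraries thinned; the cause was not tested. The median of ratios, a prior count of 5, and the added unique plus multi-matches and GC and length correction moved no count by over 1.5 times. Of the 257 calls of named miRNAs 232 were kept as CPM of the total, 249 by the median of ratios, 225 without the stem cell clusters, 194 thinned and 186 at a log2 of 1.5.

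As CPM of the library's total, 25 miRNAs were higher in untreated Wt1 KO against WT, 124 higher and 34 lower with RA in Wt1 KO, 42 lower in Wt1 KO against WT with RA, 35 higher and 13 lower at dox 12 h, 31 higher at dox 24 h, 125 higher and 28 lower in the difference of the RA response, and 20 returned toward WT at 12 h. As CPM of the total without the miR-290 and miR-302 clusters the counts were 26 higher in untreated Wt1 KO, 42 lower with RA in Wt1 KO, 38 lower in Wt1 KO against WT with RA, 44 higher and 9 lower at dox 12 h, 37 higher and 6 lower at dox 24 h, 5 lower at 24 h against 12 h, 131 higher and 23 lower in the difference of the RA response, and 22 returned at 12 h. TMM without the Wt1 KO library with RA, an added alternative, gave 5 lower at 24 h against 12 h.

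With a mean count of at least 10, 29 were higher at dox 12 h, 34 higher and 29 lower at dox 24 h, 14 lower at 24 h against 12 h, and 21 and 23 returned toward WT at 12 h and 24 h. With a mean count of at least 200, fewer miRNAs remain to be counted: 21 higher and 32 lower in untreated Wt1 KO, 46 lower with RA in WT, 40 higher in Wt1 KO against WT with RA, 7 higher and 15 lower at dox 12 h, 11 and 7 at dox 24 h, 8 higher at 24 h against 12 h, 50 higher in the difference of the RA response, and 3 and 8 returned. Without a minimum, 66 were higher in untreated Wt1 KO, 120 higher and 157 lower with RA in WT, 103 higher in Wt1 KO against WT with RA, 35 higher at dox 12 h, 39 higher and 38 lower at dox 24 h, 23 higher and 23 lower at 24 h against 12 h, and 22 and 27 returned.

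With all libraries thinned to the smallest total, which widens the intervals, 23 were higher in untreated Wt1 KO, 46 higher with RA in WT, 44 lower in Wt1 KO against WT with RA, 12 higher at dox 24 h, 7 higher at 24 h against 12 h, 26 lower in the difference of the RA response, and 8 returned at 24 h. A size rule of 1.5 counts fewer by construction: 20 higher in untreated Wt1 KO, 45 higher with RA in WT, 44 lower in Wt1 KO against WT with RA, 4 higher and 4 lower at dox 12 h, 7 and 5 at dox 24 h, 2 higher at 24 h against 12 h, 43 lower in the difference of the RA response, and 2 and 7 returned. Depth limits the Wt1 KO library with RA, in which 10 analysed miRNAs had no read.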

Other observations

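All of the tests that weigh explanations in this part were chosen after the results were seen. The remaining lists are described here. The list named kidney-enriched has 12 measured members, most of them arms of the miR-30 family, and its name is no evidence of a kidney response. Of these members 2 were higher after 12 h of dox (median 0.36, percentile 97.3) and 1 after 24 h (median 0.40, percentile 99.0), with miR-211-5p at 1.31 and 1.79. In untreated Wt1 KO against WT 1 member of this list was higher, and the median of 0.07 flips sign with the scaling. Among the 6 neural miRNAs, miR-124-3p, at 2.29 [1.70 to 2.98], and miR-9-5p, at 1.08, were higher in untreated Wt1 KO, while the list median of 0.18 flips sign with the scaling. The 5 miRNAs reported to target pluripotency factors had positive ratios in untreated Wt1 KO, 2 of them past the size rule (median 0.81, percentile 97.0), and miR-134-5p was at -1.10 after 12 h of dox. Of the miR-15/16 family 2 of 8 were higher in untreated Wt1 KO (median 0.24, which flips sign with the scaling), and 2 were higher and 2 lower with RA in WT. In the miR-130 and miR-301 family, miR-301a-3p was higher with RA in both genotypes, at 1.71 in WT, and none of 5 members passed the size rule in untreated Wt1 KO or with dox. Among the 5 miRNAs of non-canonical biogenesis 3 were lower with RA in Wt1 KO (median -1.27, percentile 5.90), and 1 after 12 h of dox (median -0.86, percentile 2.04). The miR-34 and miR-449 list had 2 of 3 members higher with RA in each genotype, with medians of 1.32 in WT and 2.13 in Wt1 KO. In untreated Wt1 KO against WT, miR-34b-3p and miR-34c-5p were lower. Of the entries reported to overlap rRNA or tRNA, miR-6240 alone had enough reads, at -0.56 in untreated Wt1 KO and -0.32 with RA in WT.

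Sets of paralogs are given here that were picked after their values were seen, so differences between them were not tested. In untreated Wt1 KO, 3 of 3 measured mature miRNAs of miR-181a and miR-181b were lower (median -4.15), against 0 of 3 of miR-181c and miR-181d (median -0.14), which lie in another cluster. Of the X-linked cluster from miR-106a to miR-363, 5 of 7 members were higher in untreated Wt1 KO (median 1.79) and 7 of 7 lower with RA in WT (median -3.65). Its paralog from miR-17 to miR-92a-1, counted without miR-92a-1-5p (lower, at -3.71), had 2 of 5 higher in Wt1 KO (median 0.99) and none past the size rule with RA in WT, and the paralog from miR-106b to miR-25 had none of 6 past it in either.

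The 54 miRNAs that were lower in untreated Wt1 KO were weighed as a group. Reads carried over from the WT library with RA into untreated WT are argued against, since they could supply a median of 0.122% and at most 4.13% (miR-100-5p) of these miRNAs' reads there. Fibroblasts or other mesenchymal cells in the WT culture cannot be told apart, since 5 of 7 fibroblast list members and miR-133a-3p, of the muscle list, are among the 54. Of 3 markers (miR-199a/b-3p, miR-143-3p and miR-133a-3p) only 1, miR-143-3p, was higher in Wt1 KO under all 4 scalings. The interval of miR-199a/b-3p, at 0.68 [0.16 to 1.24], reached 0 as CPM of the total [-0.20 to 0.88]. miR-214-3p, a fibroblast list entry below the minimum count, had 1 read in untreated WT and 0 in Wt1 KO, and so gave no sign of such cells. A first test, on miR-199a/b-3p and miR-143-3p with TMM alone, had argued against such cells and was replaced once its result was known. A state of the WT culture like that under RA is argued against as the account for all members. Of the 54, 13 were lower with RA in WT, against 13.1 for independent lists. For the 16 that were higher with RA, against 12.2 for independent lists, such a state cannot be told apart. Both contrasts use the same untreated WT library, whose error would add to the 13 and take from the 16. The numbers for independent lists do not allow for this. Across all miRNAs the ratios of Wt1 KO against WT and of RA in WT had r of -0.22, or -0.21 with the shared WT reads split. Their covariance was -0.57, or -0.55 with these reads split. Counting error alone gave r of 0.70 in simulations, but the depths of the libraries set that value, so it is no expectation for these data. The negative r may reflect the 20 of 43 miRNAs higher in Wt1 KO that were lower with RA (10.4 for independent lists). Absence of Wt1 stays open as a hypothesis.

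The single miRNAs with the strongest dox ratios, miR-92a-1-5p, miR-409-5p and miR-501-3p, were weighed too. A change of the primary transcript is argued against by 16 other miRNAs of the same clusters, which all lay between -1.30 and 1.01 at 12 h. The 5 from the miR-17 to miR-92a-1 cluster ran from -1.30 to 0.07. The pooled median of the 16, -0.040, says little, since miR-92a-1-5p rose while the other 2 fell. Only miR-409-3p, at -0.36, was the other arm of a miRNA named above. Reads moved between near-identical entries cannot be weighed by the 0 multi-matches beside 24701 unique reads. A read placed at a near-identical entry would still be a unique match, and the mismatches allowed are not given. For miR-92a-1-5p the untreated Wt1 KO library is a candidate source of the ratio, since the lowest of the 5 other libraries was 7.34-fold above it. That does not hold for the other 2, whose levels in untreated Wt1 KO, 374 for miR-409-5p and 529 for miR-501-3p in normalised CPM, lie between those of the 2 WT libraries, while both dox libraries and Wt1 KO with RA hold at most 85.5 of either. Of the 351 miRNAs only these 2 split the libraries this way by more than 2-fold, and the cause stays open. Wt1 KO with RA received no dox, so dox-induced Wt1 cannot account for its low levels, 64.8 for miR-409-5p and 55.5 for miR-501-3p. These rest on few reads, as 3 counts in that library equal 27.8. For the dox libraries alone dox-induced Wt1 stays open, beside a difference between lines.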
